A study of Homo sapiens with 4 samples.

How the data were processed

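Total RNA was extracted with TriZol from DLD-1 and HT-29 cells grown in RPMI1640, and per the labels amino allyl aRNA was made with an Ambion kit and coupled to Cy3 or Cy5. Each line had 1 array with treated RNA in Cy5 and 1 with the dyes exchanged. The deposited scanner files hold, for each of 30336 spots in 48 printed blocks, the intensity, local background and background SD of both channels on a linear scale, and the intensity after local background was subtracted by the authors. They also hold the authors' log2 ratio of channel 1 over channel 2, shifted by 1 constant per array so that its median over spots marked valid is 0. The deposited series table holds the same log2 values with the sign reversed, log2 of channel 2 over channel 1, not turned on the dye-exchanged arrays. Scanner, software and its settings are not given in the sources used here. The methylation-specific PCR that the series text mentions was not analysed here.

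Values were recomputed from the scanner files in R 4.3.3 with limma 3.58.1. Background was corrected with normexp and an offset of 50, and 1 loess curve per array was fitted with control spots and spots marked bad given no weight. Of the spots, 29640 were not controls, and 49 were marked bad on some array and left out. A probe counted as above background where its intensity exceeded the local background by more than 2 background SD. Probes entered a comparison where at least 1 channel was above background on every array it used. Median local background in channels 1 and 2 was 334 and 275 on DLD-1 array 1, 94.2 and 545 on DLD-1 array 2, 359 and 64.0 on HT-29 array 1, and 343 and 567 on HT-29 array 2. Empty-spot medians in the same order were 260 and 177, 16.3 and 470, 281 and 26.0, and 111 and 373. Both channels were above background at 19549, 22840, 20049 and 22979 probes, and at most 2 spots of any channel were saturated. Position in the 48 blocks accounted for 45.2%, 31.5%, 23.2% and 49.7% of the variance of the log2 ratios.

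Background and the shared sign of the strongest probes decided how the dye-exchanged arrays were read; the deposited ratios keep 1 channel order and cannot decide it. With file channel 2 as treated everywhere, the Cy3 side is channel 1 on the arrays with treated RNA in Cy5 and channel 2 on the dye-exchanged ones, and it has the higher background on all 4. Under this reading the log2 ratios of the 2 DLD-1 arrays had r = −0.45 across 18868 probes, those of the 2 HT-29 arrays 0.00, and those of the 2 arrays with treated RNA in Cy5 0.51. With block medians set to 0 these became −0.23, −0.14 and 0.37. Probes are not independent replicates.

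Gene names came from the platform table, where 14200 probes carried 1 symbol, 447 several and 14993 none, and from the scanner files' descriptions for 1362 of the latter. Symbols were brought to current names with the human reference annotation of assembly GRCh38.p14, used for names only. Of 7821 probes with both sources, 7747 had the same symbol, and 15562 probes were named for 13014 genes. XAGE1D and GAGE7 are older symbols that the reference does not hold as current. GAGE7, a member of the fixed cancer-testis list, was at first lost in this matching, and the matching was mended after the values were seen, which moved that list's results.

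The 2 dye orientations of a line were averaged, and limma's lmFit and eBayes tested the 2 line means against 0, two-sided, with Benjamini-Hochberg adjustment over all probes or genes tested. Several probes of a gene were averaged. With 2 line means an exact sign-flip test cannot go below a two-sided p of 0.5, so the test rests on the variance that limma shares between probes, which it took as 1 value (SE 0.221 per probe). Treated and untreated RNA were compared within each array, and arrays of the 2 lines were not paired with each other. Within a line there is no p, and a probe was counted where the log2 ratio was at least 1 in size with the same sign on both arrays. The number that passes in the dye direction, and the number that independent arrays of the same spread would give, stand beside it. A probe counted as switched on where the untreated channel was not above background on either array, the treated channel was on both, and the ratio was at least 2 on both. Its fold is a bound, with any dimmer signal raised to the lowest that counted as above background on that array. Lowered genes with treated signal at background were bounded likewise. The level holds for a whole array and not for each probe, so the bound is not strict. PYGL and TRAPPC2L in DLD-1 lay above it, so their folds are as measured.

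The steps were tested on simulated arrays made from the spreads of these 4 arrays, in which 200 of 18868 probes were changed, 50 for each fold. Each changed probe was given the same change in both lines. Recovery of changes in 1 line alone by the limma test was not examined. The limma test over both lines recovered 26% of probes changed 1.5-fold, 84% at 2-fold, 100% at 4-fold and 100% at 8-fold. It also called 34 of 18668 unchanged probes, more than the adjusted threshold allows. In 20 sets with no changed probe it called 0 to 9, with a median of 1 and a largest absolute log2 change of 1.24. Simulated line means were limited to 4 MAD in both lines, which sets that largest change. It is therefore no upper limit of noise, and the counts of these sets may be too low. The 2-fold rule recovered 0%, 12%, 96% and 100% in DLD-1, with 0 unchanged probes passing (simulated line means were limited to 4 MAD, under 2-fold there, so none could), and 6%, 18%, 90% and 100% in HT-29, with 50 unchanged probes passing (0.268%). The spread of line means (MAD) was 0.214 in DLD-1 and 0.407 in HT-29.

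The comparisons, the alternatives and 19 gene lists were fixed before the data were examined, apart from 3 alternatives chosen after seeing the data, namely the labels' channel order, block medians set to 0 and loess within each block. The lists were cancer-testis and germline, interferon-stimulated, antigen presentation, genes reported as promoter-methylated in colorectal cancer, metallothioneins, p53 targets, cell cycle, DNA methylation and histone enzymes, deoxycytidine metabolism, imprinted, intestinal differentiation, WNT targets, adhesion and epithelial-mesenchymal, stress and inflammation, ribosomal protein, cholesterol synthesis, and fibroblast, leukocyte and endothelial markers. Each list's median was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. Genes were named by a fixed rule: up to 10 raised and 8 lowered with 1 sign on all 4 arrays, ranked by the smallest absolute ratio; up to 6 raised and 4 lowered per line, ranked likewise; up to 4 with opposite signs in the lines; 2 to 4 members of each list by the mean over both lines; and the DNA methyltransferases DNMT1, DNMT3A and DNMT3B. Genes named outside it are said to be chosen after their values were seen.

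Other settings tried were no background correction, an offset of 0, median centring, scaling between arrays, no filter, both channels above background, spots marked bad kept, the authors' series table, each array left out, arrays as samples with a dye term, an adjusted p of 0.10, eBayes with trend and robust, a 1.5-fold rule, a rule on the mean of both orientations, and the brightest probe of a gene. Figures were drawn with matplotlib 3.10.9.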

Results

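RNA from DLD-1 and HT-29, both human colorectal cancer lines, was compared with and without exposure to 5-aza-2'-deoxycytidine, a nucleoside analogue that traps DNA methyltransferases on DNA and lowers methylation as cells divide. Cells grew for 24 h and then spent 96 h with 1 µM of the drug, and untreated cells of the same line were the reference. Treated and untreated RNA of each line shared 2 oligonucleotide arrays of 30336 spots, with the dyes exchanged on the second, which gave 4 arrays. The labels do not say whether arrays or lines came from separate cultures, so the 2 arrays of a line were counted as 1 replicate. Values per line are the mean ± SD over those 2 hybridisations. At least 1 channel exceeded background at 22104 and 25825 probes on the DLD-1 arrays and at 25083 and 24619 probes on the HT-29 arrays. The number of arrays limits the precision of every value.

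Which file channel holds the treated RNA on the dye-exchanged arrays is not settled by the sources used here. The labels list treated RNA there as Cy3 and as the first channel, while the columns of the scanner files name no dye. Channel 2 was taken as treated on all 4 arrays as a working reading. It was chosen in part because under it the Cy3 side has the higher local background on 4 of 4 arrays; that agreement is built into the choice, scanner gain can also set it, and it does not support the reading. The choice was made after the files, with their strongest probes, had been seen. Every sign on a dye-exchanged array rests on it, and the main counts are given under both readings.

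The comparison over both lines asked which genes were higher or lower after the drug on the mean of the 2 lines, which a gene can pass on 1 line alone. Under the working reading, which the strongest probes helped to choose, genes normally transcribed in germ cells led the increases. In the labels' channel order 57 genes were raised, and 0 of the 36 tested cancer-testis list genes were among them. PAGE5, a cancer-testis antigen, was 7.96-fold higher in treated DLD-1 cells (log2 ratio 2.99 ± 0.14) and 12.2-fold higher in treated HT-29 cells (3.61 ± 0.56). MAEL, a germ-cell protein of the piRNA pathway that restrains transposons, was 7.80-fold higher in DLD-1 (2.96 ± 0.99) and 4.45-fold higher in HT-29 (2.15 ± 0.77). The cancer-testis antigen XAGE1D was 5.73-fold and 3.24-fold higher, and GAGE7 of the same antigen family was 2.79-fold and 2.98-fold higher. UCHL1, a ubiquitin hydrolase abundant in neurons, was 5.70-fold higher in DLD-1 and 2.12-fold higher in HT-29. Untreated signal was above background on only 1 of 2 DLD-1 arrays for PAGE5, MAEL, XAGE1D and UCHL1, and on 1 of 2 HT-29 arrays for MAEL and UCHL1, so these folds rest partly on signal at background.

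MYL2, the regulatory light chain of cardiac myosin, was 3.83-fold and 2.40-fold higher in DLD-1 and HT-29, and HSPA5, the main chaperone of the endoplasmic reticulum, was 1.57-fold and 2.49-fold higher. Each of these 7 genes had a positive ratio on 4 of 4 arrays and rose in the limma test on the 2 line means, from PAGE5 (mean log2 ratio 3.30, SE 0.216, adjusted p = 3.24e-48) to HSPA5 (mean 0.99, adjusted p = 0.00353). Of the other genes ranked among the top 10, KRT71 (adjusted p = 0.0520), LEPR (adjusted p = 0.123) and PNPLA8 (adjusted p = 0.621) did not pass, and the 2 KRT71 probes differed, with DLD-1 means of 2.25 and −0.20. The first of these probes passed the limma test over probes (mean 1.63, adjusted p = 5.35e-10), and the KRT71 gene value averages both. Among the 8 genes that ranked highest for a decrease, PCLAF, a PCNA-binding protein of DNA replication, fell, with a log2 ratio of −0.74 ± 0.03 in DLD-1 and −1.03 ± 0.87 in HT-29 (adjusted p = 0.0194). MKI67, the proliferation marker Ki-67, had a mean log2 ratio of −0.82 and did not pass (adjusted p = 0.0520). MRPL22, KRT14, GML, SLC14A1, UBE2V2 and VCAM1 had means between −0.69 and −0.39 and did not pass either. Changes by gene are shown in the plot of genes with 1 sign on all 4 arrays.

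**Figure D1:**
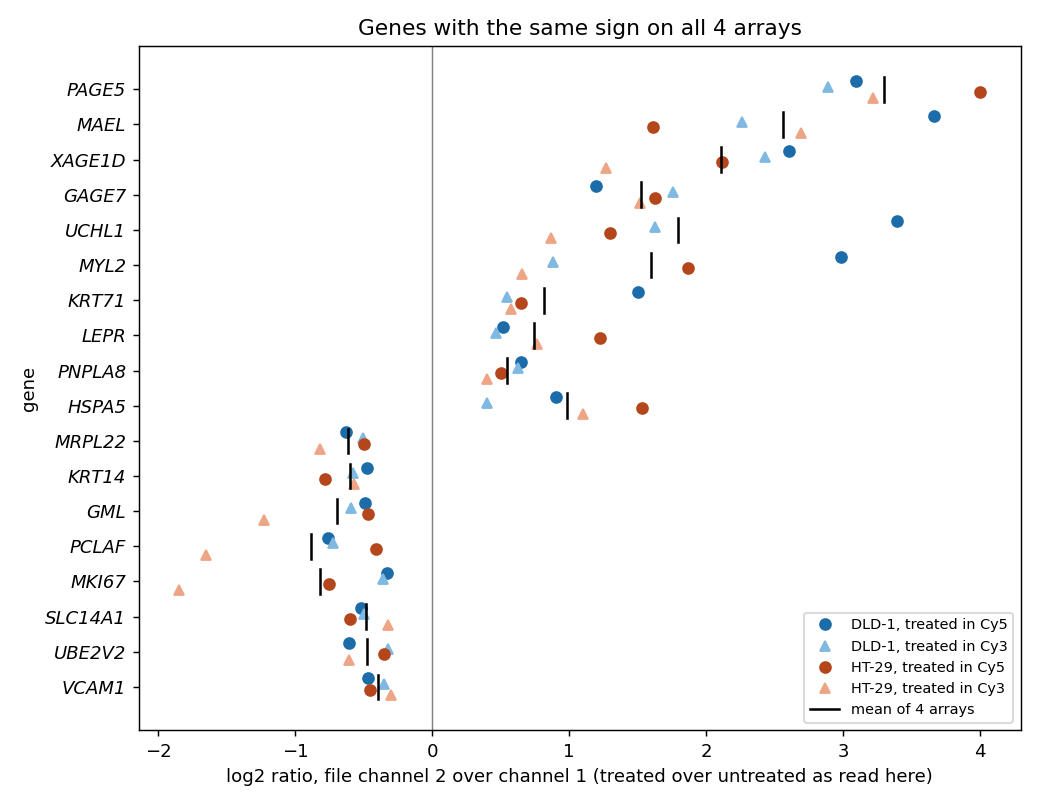
Log2 ratio of file channel 2 over channel 1 on each of the 4 arrays (x axis) for the genes that ranked highest with the same sign on all arrays (y axis). Circles mark arrays with treated RNA in Cy5, triangles the dye-exchanged arrays and black bars the mean of 4 arrays; PAGE5 has the highest mean, 3.30. Triangles would change sign if the dye-exchanged arrays were read in the labels' channel order.

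Over 18868 probes, limma called 27 probes up and 6 down at an adjusted p under 0.05, and 26 of these 33 had 1 sign on all 4 arrays. They included 22 probes of 21 named genes. Summarised to 9100 genes, 17 were up and 4 down, and 718 genes (7.89%) had the same sign on all 4 arrays, where chance gives 12.5%. The limma fit found 1 shared variance for all probes, so the very small adjusted p values follow the size of the mean alone. With the median of each printed block set to 0 on each array, 4 probes were up (PAGE5, MAEL, XAGE1D and GAGE7) and 0 down, with 1007 at an unadjusted p under 0.05, while reading the dye-exchanged arrays in the labels' order gave 126 up and 9 down, 3 of them shared with the 33, and left PAGE5, MAEL, XAGE1D and GAGE7 at means of 0.25, 0.08, 0.26 and −0.11 that did not pass. The counts up and down were 9 and 0 without DLD-1 array 1, 631 and 242 without DLD-1 array 2, 13 and 7 without HT-29 array 1, and 1 and 0 without HT-29 array 2.

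In DLD-1, TKTL1, a transketolase-like enzyme, was 12.5-fold higher in treated cells (log2 ratio 3.64 ± 1.66), with untreated signal above background on 1 of 2 arrays. VCX, a testis-expressed gene of the X chromosome, was 8.52-fold higher (3.09 ± 0.16). IFITM1, an interferon-induced membrane protein, was at least 5.21-fold higher and DKK1, a secreted WNT antagonist, at least 4.94-fold. PYGL, the liver form of glycogen phosphorylase, was 3.30-fold higher as measured, with untreated signal not above background on either array. ADRB3, a beta-adrenergic receptor, was 2.95-fold higher (1.56 ± 0.29). VCX, ADRB3 and DKK1 also passed the limma test over both lines, with HT-29 log2 ratios of 1.06 ± 1.02, 0.70 ± 0.94 and −0.49 ± 1.04. Lower values were seen for WHRN, a scaffold protein of hair cells (at least 2.49-fold lower), GPKOW (at least 1.72-fold) and TRAPPC2L (2.04-fold as measured). Treated signal of these genes was not above background on either array, so the folds of WHRN and GPKOW are bounds. POP4, a subunit of RNase P, had −0.72 ± 0.04, with treated signal above background on 1 of 2 arrays.

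Of 21218 DLD-1 probes, 24 were at least 2-fold higher and 2 at least 2-fold lower in both dye orientations, with no p because the line is 1 replicate. The lower ones were WHRN and EIF5B, a translation initiation factor chosen after its values were seen. CRIP1, CKB, RANBP9 and PRAC1, also chosen afterwards, were among the higher ones. In the dye direction 78 and 3 probes passed. They are the background of the method under the main reading, and the treatment count under the labels' channel order. Independent arrays with these spreads would give 4.99 up and 14.1 down. Across the 21218 probes, which are not independent replicates, the ratios of the 2 arrays had r = −0.41, and counts up and down on 1 array alone were 562 and 1069 without array 1, and 625 and 353 without array 2.

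In HT-29, 2 of 49 measured genes of intestinal epithelial differentiation were at least 2-fold higher, against 0 of 39 in DLD-1, a difference that was not tested. The measured genes differ between the lines. Over the 39 list genes measured on all arrays, the HT-29 median log2 ratio was 0.14, at percentile 86.8 of random lists. This lay inside their central range (−0.11 to 0.21), so the 2 genes do not show a shift of the list as a whole. FABP1 was not above background in either channel of the DLD-1 arrays, so it could not be counted there. FABP1, a fatty acid binding protein of enterocytes and hepatocytes, was 2.74-fold higher (log2 ratio 1.46 ± 0.19, untreated signal above background on 1 of 2 arrays) and KRT20, a keratin of mature intestinal cells, was 3.25-fold higher (1.70 ± 0.79). CTSE, the aspartic protease cathepsin E, had 1 probe at 2.61 and 2.60 on the 2 arrays, at least 2.82-fold higher, and another at 1.04 and −0.14. ISG15, an interferon-induced ubiquitin-like protein, was 2.84-fold higher (1.51 ± 0.60), CCT8L2 was 2.15-fold higher and DHRSX, a dehydrogenase, at least 2.14-fold higher. Lower values were seen for NCAPD2, a condensin subunit (−2.36 ± 1.60), ANXA13, an annexin of intestinal cells (−1.39 ± 0.48), PIR (−1.11 ± 0.12, treated signal above background on 1 of 2 arrays) and NMI (−1.08 ± 0.12). NCAPD2 passed the limma test over both lines (adjusted p = 3.95e-05) although its DLD-1 value was −0.01 ± 0.35.

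Of 22646 HT-29 probes, 26 were at least 2-fold higher and 3 at least 2-fold lower in both orientations, the lower ones being NCAPD2, ANXA13 and PIR. CD55, which restrains complement on cell surfaces and was chosen after its values were seen, was among the higher ones with both of its probes (means 2.05 and 1.24). In the dye direction, again the count under the labels' order, 69 and 1 probes passed. Independent arrays with these spreads would give 18.7 up and 4.25 down, and 20 sets of simulated HT-29 arrays with no changed gene gave 41 to 57 such probes among 18868, where the data gave 24 up and 2 down. That simulation passes more probes than the data, so it overstates the noise and does not show whether the HT-29 count exceeds it. With block medians set to 0, 11 up and 5 down were found against 2.67 and 2.17 for independent arrays, and counts on 1 array alone were 482 and 539 without array 1, and 1100 and 267 without array 2.

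PAGE5, MAEL, XAGE1D, GAGE7 and 1 probe without a gene name were at least 2-fold higher on all 4 arrays, as the plot of the paired arrays shows. They were the whole overlap between 16 such probes of DLD-1 and 24 of HT-29 among the 18868 measured in both, where independent lists would share 0.0204. The shared sign of the strongest probes helped to choose the reading of the arrays, so this overlap is partly built in and its excess is no evidence for it. No probe was at least 2-fold lower in both lines, where 0 in DLD-1 and 2 in HT-29 qualified, and 0 were 2-fold higher in 1 line and lower in the other. Across those probes the line means had r = 0.07 and rho = 0.06; probes are not independent replicates. In the labels' channel order 2 probes were shared between 72 and 62, where 0.237 would be by chance, and with any 1 array left out 5 to 10 were shared, 10 of them without DLD-1 array 2 or HT-29 array 2.

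**Figure D2:**
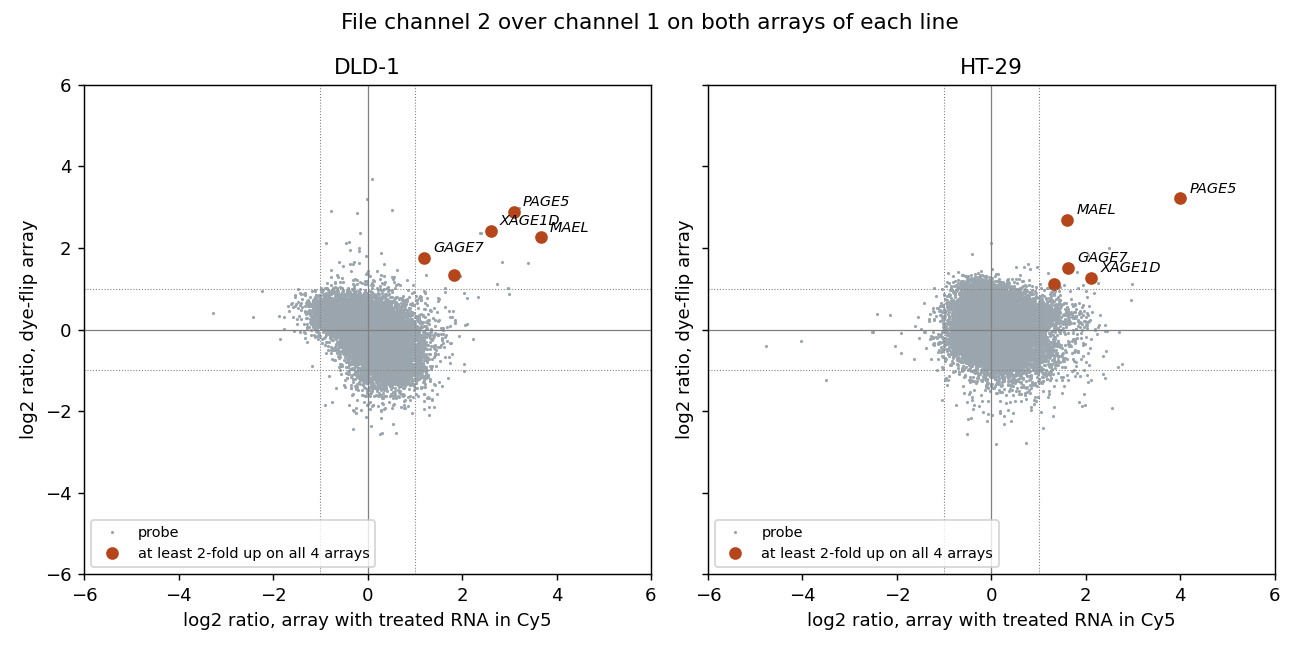
Log2 ratio of file channel 2 over channel 1 for each of 18868 probes (grey) on the array with treated RNA in Cy5 (x axis) and on the dye-exchanged array (y axis), for DLD-1 (left) and HT-29 (right). The 5 orange probes, 4 of them named, are at least 2-fold up on all 4 arrays; dotted lines mark 2-fold, and the y axis would change sign in the labels' channel order.

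The study looked for silenced genes that the drug switches on. In DLD-1, 5 probes had untreated signal at background on both arrays and treated signal above it with a ratio of at least 2 on both. Among them were IFITM1, DKK1, PYGL and MTERF1, a mitochondrial transcription factor (at least 1.99-fold). In HT-29 there were 4, CTSE, DHRSX, HLA-F, a nonclassical class I molecule (at least 3.16-fold), and 1 unnamed probe (at least 1.63-fold). MTERF1 was chosen after its values were seen. These are calls of single probes, and the other probe of CTSE and of HLA-F was above background on both untreated HT-29 arrays, so neither gene as a whole was off. The log2 ratios of the other HLA-F probe were −0.78 and −0.31, and DKK1, off in untreated DLD-1, was above background in untreated HT-29 with a ratio of −0.49 ± 1.04. The labels' channel order gave 18 probes in DLD-1 and 14 in HT-29, and 1 array alone gave 257 without DLD-1 array 1, 230 without DLD-1 array 2, 58 without HT-29 array 1 and 456 without HT-29 array 2.

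Gene groups fixed before the data were examined were compared with 10000 random lists of like signal, as the plot of list medians shows. Of 36 cancer-testis and germline genes measured on all arrays, 3 rose over all genes tested (PAGE5, MAEL and GAGE7) and 5 when adjusted over the list alone, where MAGEB2 (mean log2 ratio 0.63) and HORMAD1 (0.60, chosen after its values were seen) joined them. The other genes of the list did not pass, and the list median of 0.07 lay at percentile 92.2 of random lists. That median was 0.10 at percentile 99.9 with block medians set to 0 and turned to −0.10 at percentile 0.28 in the labels' channel order. Of 40 list genes measured in each line, 4 were at least 2-fold higher in DLD-1 and 3 in HT-29.

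Among 32 interferon-stimulated genes the median log2 ratio was 0.18, at percentile 99.97, with 0.11 in DLD-1 (percentile 99.8) and 0.21 in HT-29 (percentile 95.1). No member passed limma over all genes tested, where 456 genes had an unadjusted p under 0.05, and 1, ISG15 (mean 0.74, with −0.03 in DLD-1 and 1.51 in HT-29), passed when adjusted over the list alone. RIGI (0.62), UBE2L6 (0.50) and IFIT1 (0.48) did not pass, and 4 members were positive on all 4 arrays. In the labels' channel order the list median was 0.09 at percentile 73.8.

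Among 58 genes reported as promoter-methylated in colorectal cancer, UCHL1 and DKK1 rose, both over all genes and adjusted over the list alone, and 56 did not pass. DKK1's mean of 0.94 came from DLD-1. CDKN2A, which encodes the cell cycle inhibitor p16 (0.53), and GPX3 (0.47) did not pass, and the list median of 0.02 lay at percentile 63.2.

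The 55 cell cycle genes had a median of −0.15 at percentile 0.01, with −0.09 in DLD-1 (percentile 17.5) and −0.21 in HT-29 (percentile 0.01). None passed over all genes tested with limma. Adjusted over the list alone 4 fell, namely MKI67 (−0.82), MCM6 of the replicative helicase (−0.71), the mitotic kinase CDK1 (−0.64, with 0.06 in DLD-1 and −1.34 in HT-29) and cyclin CCNB2 (−0.63, with −0.09 and −1.17), and 9 members were negative on all 4 arrays. On HT-29 arrays 1 and 2, MKI67 had −0.75 and −1.85, CDK1 −0.50 and −2.19 and CCNB2 −0.39 and −1.95. The HT-29 falls of these genes thus came mainly from array 2, while MCM6 had −0.96 and −1.18. Treated signal of MKI67 and CDK1 was above background on 1 of 2 HT-29 arrays. In the labels' channel order the cell cycle median turned to 0.13 at percentile 97.1. The 69 ribosomal protein genes had a median of −0.08, below all 10000 random lists of equally bright genes (the central 95% ran from 0.03 to 0.15). This came from HT-29, with −0.14 at percentile 0, while DLD-1 had −0.01 at percentile 8.85, inside its random range. The list median was −0.03 at percentile 1.85 in the labels' order. None passed, with RPS15 at 0.58, RPS13 at −0.51, RPL22 at −0.42 and RPL11 at −0.41.

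Among 28 DNA methylation and histone modification enzymes none passed, over all genes or adjusted over the list alone, and the median was −0.04 at percentile 17.4. DNMT1, the maintenance methyltransferase that the drug traps, had a mean log2 ratio of −0.27, DNMT3A 0.11 and DNMT3B −0.05 (limma adjusted p between 0.988 and 0.996), and the DNMT1 mean was 0.09 in the labels' channel order. The members with the largest means were SUV39H1, a histone H3 methyltransferase (−0.52), MBD4, a repair glycosylase (0.49), HDAC6 (−0.35) and DNMT3L (0.33).

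**Figure D3:**
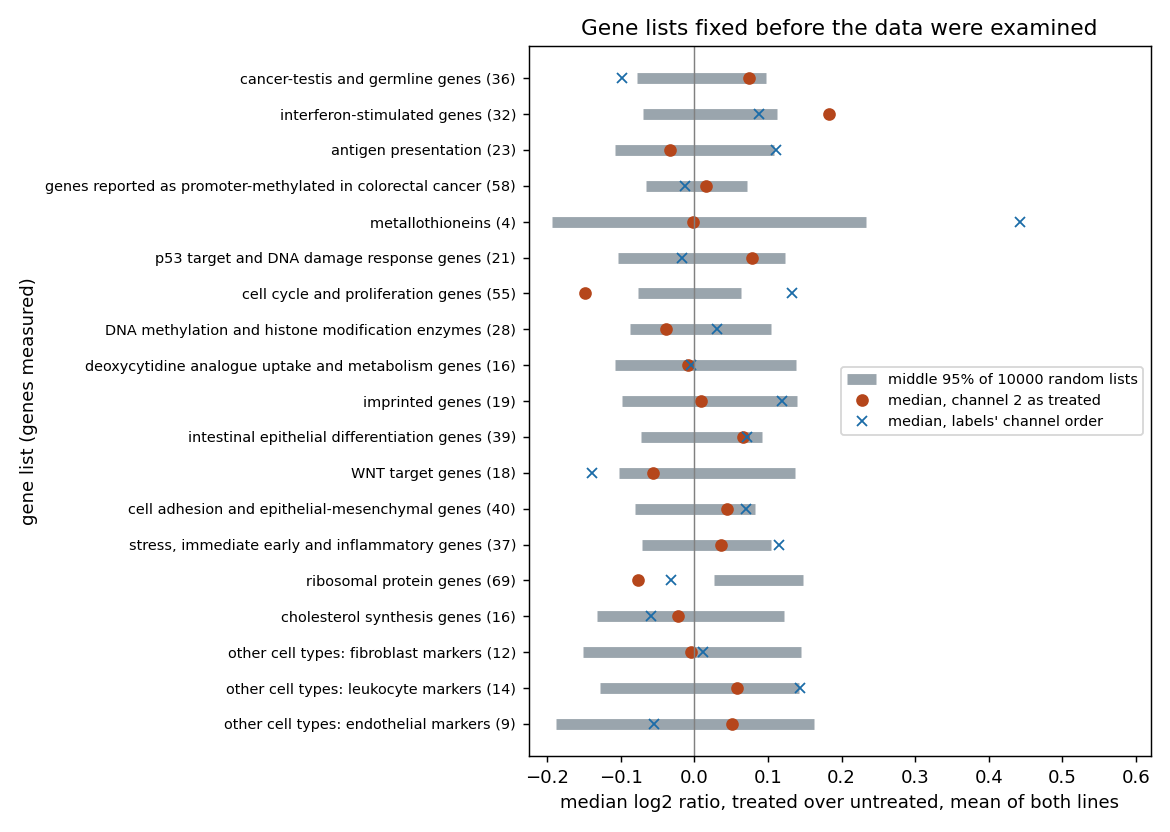
Median log2 ratio over both lines (x axis) of 19 gene lists (y axis, measured genes in parentheses). Orange circles read channel 2 as treated, blue crosses follow the labels' channel order and grey bars span the central 95% of 10000 random lists under the first reading. Under that reading interferon genes lie above the bar at 0.18 and cell cycle genes below it at −0.15, where the labels' order puts them at 0.09 and 0.13. The bars do not apply to the crosses, and in the labels' order the cell cycle median lay at percentile 97.1.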

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

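Of the tests in this part, all but the one on the shared variance estimate were chosen after the results had been seen. Among named genes measured on all 4 arrays, the lines moved apart at 8, with both arrays of DLD-1 on one side of 0 and both of HT-29 on the other. The differences, DLD-1 minus HT-29 in log2 units, were not tested. CHST2, GDE1, CLIC3 and LY96 were named because their signs were opposite in the lines, so for them this is built in. POP4 and KRT20 were named for a change in 1 line. CHST2, a sulfotransferase, stood apart by 1.19 and the phosphodiesterase GDE1 by 1.27. CLIC3, of the chloride channel family, stood apart by 1.70 and the cholesterol synthesis enzyme SQLE by 0.82. LY96, the partner of TLR4 in sensing lipopolysaccharide, was higher in HT-29 with a difference of −0.99, the keratin KRT20 with −2.03, the phosphatase INPP5F with −1.16 and the RNase P subunit POP4 with −0.91. GDE1 has another probe with DLD-1 and HT-29 means of 0.40 and 0.06. TKTL1 had opposite signs in the lines too, but its HT-29 signal was above background on 1 of 2 arrays. All of these signs rest on the reading of the dye-exchanged arrays.

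The highest channel 2 over channel 1 ratios keep their sign on all 4 arrays, although most DLD-1 ratios change sign between its arrays. If channel 1 were Cy3 on every array, the shared sign would be a dye effect. Among 17 raised genes, 1 of 32 tested cancer-testis genes outside the PAGE, XAGE and GAGE families was found (Fisher's exact p = 0.0582, one-sided), so a dye effect on related probes and an effect of the drug cannot be told apart by this test, which rests on MAEL alone. With channel 2 read as the treated RNA throughout, Cy3 had the higher empty-spot signal on 4 of 4 arrays, but that reading was chosen from the local background, so the empty spots restate the choice and do not support it. Scanner gain could give this too, and the expression of germline genes after demethylation stays a hypothesis.

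Of the 33 probes called in the test over both lines, 4 were called with block medians set to 0. Offsets shared by a whole printed block did not make most of the log2 changes of the 33. The block-centred change was 0.875 of the original at the median and at least 0.787 of it at each of them. Effects of position within a block are not removed by this and stay open. The estimate of the variance is a candidate cause for the loss: with 1 shared variance the block-centred values gave 77 calls, all 33 among them, whereas limma estimated a prior of 9.81 degrees of freedom and so kept more of each probe's own spread, and with that prior the original values gave 7. The median log2 change of the 27 raised probes was 1.16 before and 1.11 after, and the median SD between lines over the 33 was 0.58 before and 0.54 after. For 6 of the 33 the mean change was under 0.5 in size without the array of the largest value. BLZF1, chosen after its values were seen, is among them at −4.76 on HT-29 array 1. DKK1 is too, but with 2.39 and 2.36 on the DLD-1 arrays it rests on that line and not on 1 array.

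Cell cycle genes lay below random lists over both lines. Offsets of whole printed blocks are argued against by a list median of −0.15 with block medians set to 0, at percentile 0 of random lists. The reading of the dye-exchanged arrays stays open as what sets the direction, since the median turned to 0.13 in the labels' channel order. Slower division in treated cells may underlie the lower values under the main reading, but the design holds no measure of growth, and this was not tested.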

How the results depend on the processing

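The alternatives with the labels' channel order, block medians set to 0 and loess within each printed block were chosen after seeing the data, and the others were planned. In the test over both lines 27 probes were up and 6 down. Probes up came to 47 with no filter, 126 in the labels' channel order, 4 with block medians set to 0 and 7 with loess within blocks, and from 1 (without HT-29 array 2) to 631 (without DLD-1 array 2) with 1 array left out. Probes down came to 1 with an offset of 0, 1 with scaling between arrays, 2 with both channels above background, 2 with the authors' values, 3 with arrays as samples, 3 with trend and robust, 0 with block medians set to 0 and 0 with loess within blocks, and from 0 to 242 with 1 array left out. With block medians set to 0 limma's variance prior was finite (9.81 degrees of freedom), and the values after loess per array gave 7 calls with that prior in place of 33. The prior was finite as well with loess within blocks (10.6), an offset of 0 (37.1), scaling (36.3) and without HT-29 array 2 (7.03), and 1 variance was shared by all probes elsewhere; the cause was not tested for these.

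In DLD-1, 24 probes were up and 2 down. Up there were 65 with no filter, 9 with both channels above background, 109 with the 1.5-fold rule, 67 by the mean of both orientations, 78 in the labels' order, and 562 to 625 on 1 array. Down there were 1 with no background correction, 6 with no filter, 0 with both channels above background, 1 with the authors' values, 21 with the 1.5-fold rule, 26 by the mean, 1 with loess within blocks, and 353 to 1069 on 1 array. In HT-29, 26 were up and 3 down. Up there were 12 with scaling, 41 with no filter, 15 with both channels above background, 16 with the authors' values, 329 with the 1.5-fold rule, 141 by the mean, 69 in the labels' order, 11 with block medians set to 0, 11 with loess within blocks, and 482 to 1100 on 1 array. Down there were 12 with an offset of 0, 5 with scaling, 15 with no filter, 131 with the 1.5-fold rule, 48 by the mean, 1 in the labels' order, 5 with block medians set to 0, 1 with loess within blocks, and 267 to 539 on 1 array. Looser rules pass more probes by construction, and 1 array alone cannot cancel a dye effect; for the others the cause was not tested.

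The overlap of 5 raised probes became 2 with both channels above background, 1 with the authors' values, 9 with the 1.5-fold rule, 11 by the mean of both orientations, 2 in the labels' order and 5 to 10 with 1 array left out. The 5 probes switched on in DLD-1 became 3 with no background correction, 0 with both channels above background, 0 with the authors' values, 13 with the 1.5-fold rule, 11 by the mean, 18 in the labels' order, 3 with block medians set to 0, 3 with loess within blocks and 230 to 257 on 1 array. The 4 in HT-29 became 2, 0, 0, 21, 7, 14, 2 and 2 under the same settings in that order, and 58 to 456 on 1 array. A filter on both channels, which the authors' valid marks also apply, excludes switched-on genes by construction. Of the named genes and lists with a call over both lines, those that changed sign did so in the labels' channel order alone. They were the cell cycle list (0.13), GAGE7 (−0.11) and PCLAF (0.30), and among genes called over their list alone MKI67 (0.28), MCM6 (0.13), CDK1 (0.46), CCNB2 (0.52) and HORMAD1 (−0.19), the last examined in that order only. That order turned the mean of 3 of 27 raised and 3 of 6 lowered probes over both lines, of 5 of 24 and 1 of 2 in DLD-1, and of 3 of 26 and 2 of 3 in HT-29, ANXA13 and PIR. It also turned the sign of 9 of 19 list medians, against 4 with block medians set to 0 or loess within blocks, 0 with no background correction and 3 to 7 with 1 array left out. Of 104 named values, 104 held their call and size with spots marked bad kept, 101 with no background correction, 90 with block medians set to 0 and 59 in the labels' order. Signal near background limits most folds of genes that are off in untreated cells to bounds, which are not strict.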

Other observations

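Of the 2 tests on cancer-testis genes in this part, the one against random lists that also lose genes was chosen after the results had been seen. Of 39 genes of intestinal differentiation measured on all arrays, none passed over all genes tested with limma, where 456 had an unadjusted p under 0.05, and 2 were raised when adjusted over the list alone: KRT8, a keratin of simple epithelia (mean log2 ratio 0.69), and KRT20 (0.69, with −0.33 in DLD-1 and 1.70 in HT-29). KLF4, a transcription factor of goblet cells (0.51), and the trefoil peptide TFF1 (0.47) did not pass. The list median was 0.07 at percentile 90.8 of random lists. Of 40 adhesion and epithelial-mesenchymal genes none passed over all genes and 4 were raised when adjusted over the list alone: TIMP1, a metalloproteinase inhibitor (0.70), ANXA1, a phospholipid-binding annexin (0.69), TJP1, a tight junction protein (0.68), and S100A4, a calcium-binding protein (0.64). The 2 arrays of a line differed in sign for ANXA1 in DLD-1 (1.09 and −0.43) and TJP1 in HT-29 (1.10 and −0.51). TIMP1 and S100A4 were positive on all 4 arrays, with HT-29 values of 1.56 and 0.27, and of 1.11 and 0.09. The median of the 40 genes was 0.04 at percentile 83.5, with 0.05 at percentile 99.5 in DLD-1 and −0.04 at percentile 16.6 in HT-29.

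Of 23 antigen presentation genes, HLA-F (mean 1.02, with 0.10 in DLD-1 and 1.93 in HT-29) passed over all genes, B2M, the light chain of class I molecules (0.64, with 0.16 and 1.11), only when adjusted over the list alone, and ERAP1 (0.40) and HLA-DRA (−0.38) did not pass; the median was −0.03 at percentile 25.8. Of 37 stress and inflammation genes HSPA5 passed both ways, HSP90AA1 (0.56) and ASNS (−0.51) did not, and the median was 0.04 at percentile 67.8, or 98.0 with block medians set to 0. Of 18 WNT target genes DKK1 passed both ways, BMP4 (−0.41), SOX4 (−0.33) and AXIN2 (0.30, with 3 probes that differ) did not, and the median was −0.06 at percentile 10.6. The AXIN2 value averages its probes, and 1 of them passed the limma test over probes (mean 0.92, adjusted p = 0.0214). Its other probes had DLD-1 and HT-29 means of −0.04 and 0.46, and of −0.29 and −0.17. No member of the following lists passed, over all genes or adjusted over the list alone. The 4 metallothioneins had a median of 0.00 at percentile 40.0, and 0.44 at percentile 99.2 in the labels' channel order, with MT1G at 0.28 and MT1L at −0.27. The 21 p53 target genes had 0.08 at percentile 87.7, with ZMAT3 at 0.39 and CDKN1A at −0.36. The 16 genes of deoxycytidine metabolism had −0.01 at percentile 33.3, with NT5E at 0.60 and NT5C3A at 0.45. The 19 imprinted genes had 0.01 at percentile 42.6, with USP29 at −0.32 and ATP10A at −0.28. The 16 cholesterol synthesis genes had −0.02 at percentile 38.0, with LSS at −0.59 and HSD17B7 at −0.32.

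Markers of other cell types lay within the random range. The 12 fibroblast markers had a median of −0.01 at percentile 48.5, with DCN at 0.33 and COL6A1 at −0.29. The 14 leukocyte markers had 0.06 at percentile 75.7, with CD14 at 0.32 and NKG7 at 0.30. The 9 endothelial markers had 0.05 at percentile 77.5, with PLVAP at 0.44 and EMCN at −0.32.

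The lines shared little of their change over all genes, and a hypothesis was that cancer-testis genes changed alike in both. Across the 36 measured genes of the list, which are not independent replicates, the line means had r = 0.81, at percentile 99.9 of random lists, part of which the choice of reading builds in. Without the 3 genes at least 2-fold higher in both lines r was 0.0728 over 33 genes, at percentile 55.3. The condition set down before counted this against the hypothesis, but those 3 genes were picked for agreeing, and leaving them out lowers r by construction. Among random lists that lost their 3 most alike genes too, the same r lay at percentile 83.8, inside the central 95%, so whether the rest of the list changed alike stays open.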
